A study of Homo sapiens with 22 samples.

How the data were processed

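RNA was measured in 16 libraries of CD8 T cells sorted from human tumours: 4 kidney stem, 4 kidney effector, 4 bladder stem, 2 bladder effector and 2 prostate stem libraries. Stem cells were sorted as CD8 and CD28 positive, PD1 positive and TIM3 negative, and effector cells as CD8, PD1 and TIM3 positive, per the labels. The 6 DNA methylation samples were not analysed here. RNA and DNA were extracted with the Qiagen AllPrep kit and sequenced on HiSeq machines, per the labels' protocols. The labels differ on the RNA library kits: the extraction protocol names NuGen Ovation for bladder and Clontech SMART-Seq for kidney and prostate, and the series' design text names both kits for bladder and NuGen for prostate.

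The values used were gene counts, which the authors deposited as whole numbers in 1 table for kidney and prostate (60448 genes) and 1 for bladder (60619 genes), with 60448 genes in both. The submitters' processing notes name cutadapt, DESeq2 and the hg38 build, without versions, and the aligner and counter are not given in the sources used here. Bladder columns are named by subset and number alone, so their tumour was taken from the name of the table, and 0 columns of sample values were left unused. Of 60619 gene IDs, 56434 matched a table of gene names, and 28 symbols that a spreadsheet had turned into dates were replaced through their Ensembl ID. Gene coordinates are 1-based on GRCh38, the build named hg38. XIST, TSIX and Y-linked genes, 542 IDs in all, were left out of every test and table.

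Counts were compared with edgeR 4.0.16 in R 4.3.3, with TMM normalisation, low-count filtering by filterByExpr, a robust quasi-likelihood F test (two-sided) and Benjamini-Hochberg adjustment, with 0.05 as the threshold. The standard error of a log2 fold change is its size divided by the square root of F. Levels are CPM (counts per mega-count) with the SD over libraries, and log2 CPM used a prior count of 2. Kidney stem was compared with kidney effector, bladder stem with bladder effector, the difference between these 2 effects was tested as an interaction in 1 fit of the genes in both tables, and prostate stem was compared with kidney stem in 1 fit with kidney effector. Levels in the kidney and prostate table and in the bladder table were not tested against each other. Where a group had 1 to 3 counts, the ratio of CPM is given with its 95% counting interval, and with 0 counts a lower bound against a floor of 3 counts over the group. Library kits without molecular identifiers count copies, so intervals and floors cover counting error only.

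Fixed lists of genes, 32 in all with 500 genes, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists with at least 3 genes tested in a comparison, and again with an estimated correlation and with fry. The 20 function lists were stem-like and memory T-cell genes, inhibitory receptors, exhaustion-associated regulators and markers, cytotoxic effector genes, costimulatory receptors and ligands, cytokine receptors, chemokines and chemokine receptors, tissue residency, tissue egress, cell cycle, glycolysis, oxidative phosphorylation, interferon-stimulated, MHC class II, immediate early, heat shock, DNA methylation machinery, T-cell receptor signalling, apoptosis and ribosomal protein genes. The 11 lists of other cells were CD4 helper and regulatory T-cell, B-cell and plasma-cell, myeloid, NK-cell, gamma-delta and MAIT cell, epithelial, renal epithelial and clear cell carcinoma, prostate epithelial, urothelial, stromal and endothelial, and erythrocyte markers. The last list held the gate markers and CD3D.

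Groups, tests, lists, alternatives and the rule for named genes were set before the data were examined, except where the text says otherwise. The rule named CD8A, CD8B, CD3E, CD28, PDCD1 and HAVCR2. It added the 10 largest log2 fold changes per direction among genes past the threshold whose groups did not overlap and whose mean log2 CPM was at least 2, without T-cell receptor and immunoglobulin segments, genes without a symbol, genes of common germline deletions, and HLA genes outside the lists. It also added up to 4 members of each list by smallest p and, where no gene passed, the 5 of smallest p per direction, and it followed the kidney genes into bladder. Values per library were compared by exact two-sided permutation tests. Alternatives were other size factors, low-count filters, DESeq2 1.42.0, limma-voom with quality weights, removal of abundant gene classes, a block on replicate number, a test beyond 1.5-fold, other sets of libraries in the fit, and leaving out each library in turn. A surrogate variable (sva 3.50.0) and fits without libraries rich in epithelial RNA were added after seeing the data. The edgeR and camera tests were first run on simulated counts made from the means and sizes of the real libraries, with known changes of 2-, 4- and 8-fold. The changed genes were drawn from those whose mean CPM had a log2 of at least 2, so recovery at lower levels was not simulated. Genes were simulated independently, without a library that deviates from its group.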

Results

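RNA was sequenced from CD8 T cells sorted out of human kidney, bladder and prostate tumours. The stem subset carried CD8, CD28 and PD1 and lacked TIM3, and the effector subset carried CD8, PD1 and TIM3. CD28 is a costimulatory receptor, and PD1 and TIM3 are inhibitory receptors encoded by PDCD1 and HAVCR2. The 16 RNA libraries were 4 kidney stem, 4 kidney effector, 4 bladder stem, 2 bladder effector and 2 prostate stem libraries. A further 6 samples of DNA methylation, 2 each of kidney stem, kidney effector and blood naive cells, were not analysed here.

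Total counts, in M (mega-counts), were 16.3, 69.3, 15.3 and 18.8 in kidney effector libraries 1 to 4, and 22.2, 16.2, 24.7 and 11.7 in kidney stem libraries 1 to 4. They were 22.3 and 21.5 in the prostate stem libraries, 34.4 and 22.1 in the bladder effector libraries, and 29.9, 25.1, 31.9 and 28.4 in the bladder stem libraries. Mitochondrial ribosomal RNA took 44.1% to 56.9% of the counts in the kidney and prostate libraries and 0.647% to 1.22% in the bladder libraries, so that 5.77 to 34.8 M counts were left for other genes in kidney and prostate. Libraries of 1 group differed by 24.4 to 399.6 times the sampling noise of their counts (chi-square per degree of freedom, 20 pairs), and none was a copy of another. Kidney effector libraries 1 and 3 were the most alike, at 24.4, where the other pairs of kidney effector libraries stood at 87.9 to 133.9. The labels used here do not tie the libraries of a group to separate donors, so the p-values measure the spread between these libraries.

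The first comparison set kidney stem against kidney effector libraries, 4 against 4. IL7R, TCF7, KLF3 and S1PR1 were among the genes higher in the stem libraries, and VCAM1, TOX, CD200R1, 4 of 11 MHC class II genes and the replication gene MCM5 were lower. IL7R, the interleukin-7 receptor alpha chain (ENSG00000168685, chromosome 5, 35856891 to 35879603 on GRCh38), stood at 945 ± 309.8 CPM (counts per mega-count; SD, n = 4) in stem and 84.3 ± 87.8 in effector libraries, a log2 fold change of 3.48 ± 0.69 (SE; edgeR quasi-likelihood adjusted p = 0.0494). TCF7, the transcription factor TCF1 of memory and stem-like T cells (ENSG00000081059, chromosome 5, 134108218 to 134148210), was at 68 ± 42.1 against 7.62 ± 4.56 CPM, with a log2 fold change of 3.16 ± 0.54 (adjusted p = 0.0206). VCAM1, a vascular adhesion molecule (ENSG00000162692, chromosome 1, 100719742 to 100739045), was at 27.8 ± 10.9 CPM in stem and 412 ± 131 CPM in effector libraries, and fell by 3.89 on the log2 scale (SE 0.38, and adjusted p = 0.0026). TOX, a transcription factor of exhausted T cells (ENSG00000198846, chromosome 8, 58805412 to 59119147), was at 109 ± 22.6 against 336 ± 71.8 CPM, a log2 fold change of -1.62 ± 0.24 (adjusted p = 0.0105).

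In all, 191 of 13209 genes tested passed the threshold, 108 higher and 83 lower in stem libraries, and 2003 had an unadjusted p below 0.05. The largest changes were ranked among called genes with a mean log2 CPM of at least 2 and groups that did not overlap. Called genes below that level could change more, such as ENPP5 at a log2 fold change of 6.09 ± 1.21 (edgeR adjusted p = 0.0306). The 10 largest increases so ranked began with TANC2, a scaffold protein, at 4.75 ± 0.60, and KLF3, a transcriptional repressor, at 4.57 ± 0.62. The nuclear lamina gene LMNA, the integrin gene ITGA5, the sodium pump subunit ATP1B1 and the polarity gene MPP7 followed at 4.28, 4.21, 4.08 and 4.04. S1PR1, the sphingosine-1-phosphate receptor of lymphocyte egress, rose by 3.75 ± 0.53, GPR183, an oxysterol receptor that guides lymphocyte migration, by 3.62 ± 0.50, and NHSL2 by 3.54 ± 0.52. IL7R was the tenth of these genes. Among the 10 largest decreases with the same limits were BHLHE40-AS1 (-5.05 ± 0.99), CD200R1, an inhibitory receptor (-3.27 ± 0.55), VANGL1, a planar polarity protein (-3.14 ± 0.44), and the mitotic kinase AURKA (-2.92 ± 0.63). VWA5A, SNX18, AMER1, RDH10 and PTPRF had log2 fold changes of -3.10 to -2.77. BHLHE40-AS1 lies antisense to BHLHE40 and the strand of the counts is not known, so its reads cannot be told from those of its partner. Groups did not overlap in 9.93% of the genes tested, where chance gives 2.86%, and in each of the 191 that passed.

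The markers of the sort were read first as a check of the labels. HAVCR2, which encodes TIM3, was at 16 ± 15.8 CPM in kidney stem and 292 ± 55.5 CPM in kidney effector libraries, a log2 fold change of -4.20 ± 0.96 that missed the threshold (adjusted p = 0.0829). PDCD1 had a log2 fold change of -1.27 ± 0.65 and CD28 of 1.02 ± 0.89, with adjusted p of 0.393 and 0.646. CD8A, CD8B and CD3E were at 655 ± 272, 30.6 ± 18.3 and 222 ± 74.6 CPM in stem libraries, with log2 fold changes of -0.11 ± 0.30, -0.57 ± 0.48 and -0.20 ± 0.26, none of which passed. As a list, the 7 gate markers were lower (camera adjusted p = 0.0498; median -0.20), and the call was lost with an estimated correlation (adjusted p = 0.661 with an estimated correlation). It was also lost without effector library 1 (0.0937), effector library 4 (0.0728), stem library 1 (0.164, median -0.05) or stem library 3 (0.111, median -0.10), and without stem library 2 or 4 the median was -0.355 or -0.43. Of these genes 0 passed over all genes and 1, HAVCR2, when adjusted over the list alone.

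**Figure D1:**
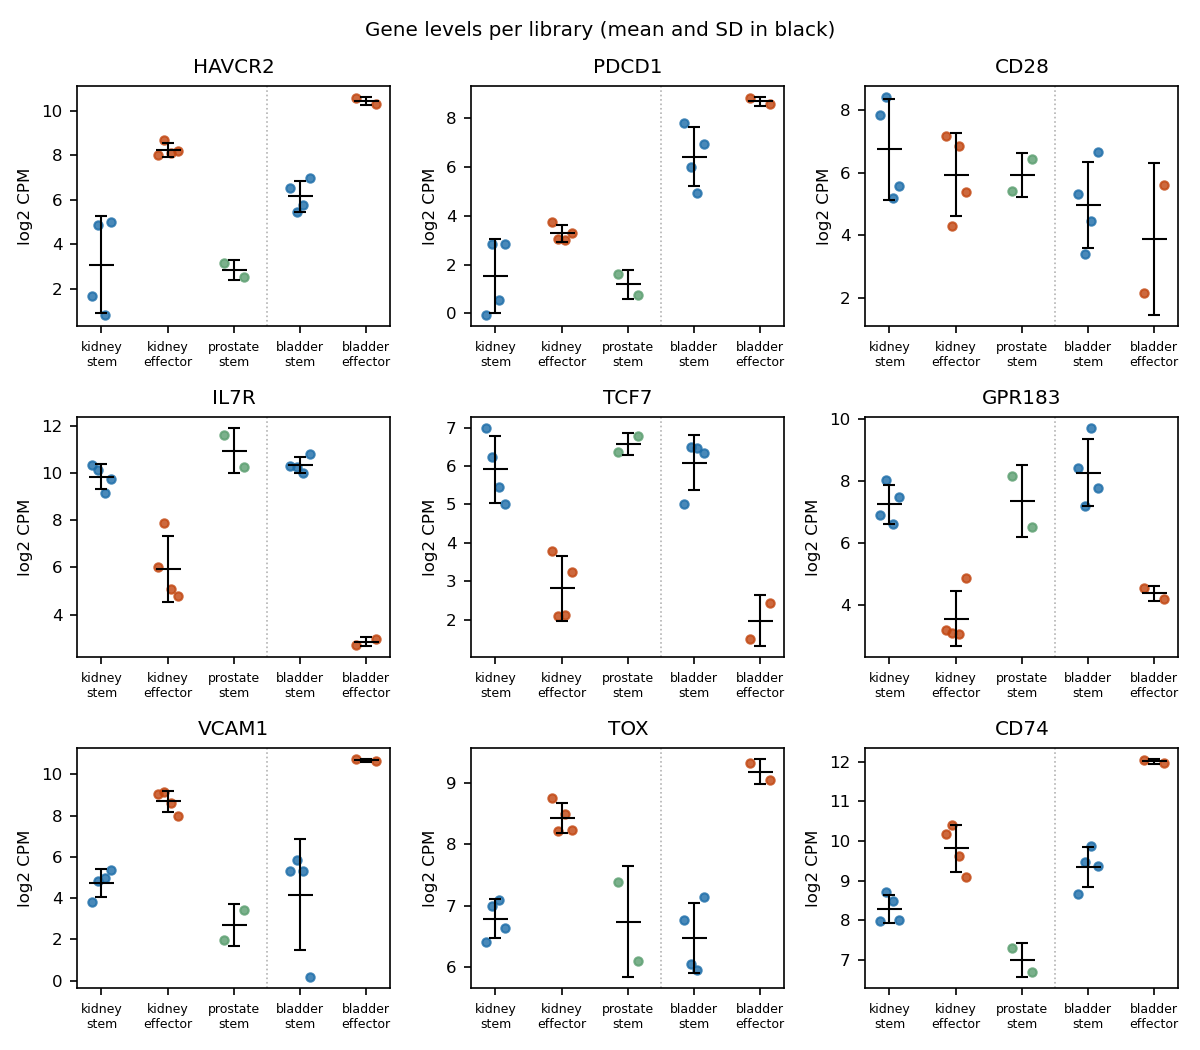
Log2 CPM of 9 genes in each of the 16 RNA libraries (points), with the mean and SD of each group in black, and a dotted line between the kidney and prostate table and the bladder table, whose levels were normalised separately. IL7R, TCF7 and GPR183 were higher and VCAM1, TOX and CD74 lower in every stem library than in every effector library of the same tumour.

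Stem-like and memory T-cell genes were higher in kidney stem libraries as a list, with a median log2 fold change of 1.16 (camera adjusted p = 0.000165, and adjusted p = 0.0928 with an estimated correlation). Of 21 members tested, 6 rose, 1 fell and 14 did not pass, and 9 rose and 4 fell when adjusted over the list alone. Besides IL7R, TCF7, KLF3 and S1PR1, the homing receptor CCR7 rose (3.47 ± 0.68), and MYB, a progenitor transcription factor, fell (-2.77 ± 0.48). Tissue egress genes had the highest median of the function lists, with 4 of 9 members higher, 0 lower and 5 that did not pass (5 higher when adjusted over the list alone; median 1.38, camera adjusted p = 2.15e-07). They included S1PR5, another sphingosine-1-phosphate receptor, at 6.28 (adjusted p = 0.0119), and the sorting receptor SORL1 at 2.47 ± 0.35. This was the 1 of 11 lists past the threshold in kidney whose call held with an estimated correlation (adjusted p = 0.0325 with an estimated correlation). By fry, 7 of the 27 lists tested in kidney passed.

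Cytokine receptors were higher as a list (median 0.13, camera adjusted p = 0.0283, and adjusted p = 0.306 with an estimated correlation). Members higher were IL7R and the interferon gamma receptor IFNGR1 (2.18 ± 0.48), 0 were lower and 19 did not pass (3 higher and 1 lower when adjusted over the list alone). This call was lost without effector library 1 (0.0647), effector library 3 (0.116) or stem library 4 (0.0842). The median was 0.052, 0.339 and 0.245 without effector library 1, 2 or 4 and -0.006, 0.229 and -0.014 without stem library 2, 3 or 4. Immediate early genes had a median of 0.68 (camera adjusted p = 2.84e-05, and adjusted p = 0.187 with an estimated correlation). In this list 0 of 20 genes were past the threshold over all genes and 7 higher when adjusted over the list alone. Ribosomal protein genes had a median of 0.69 (camera adjusted p = 3.43e-09, and adjusted p = 0.247 with an estimated correlation), with RPL3 higher (1.21 ± 0.24) among 26 genes and 15 higher when adjusted over the list alone.

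Exhaustion-associated regulators and markers were lower in kidney stem libraries (median -1.24, camera adjusted p = 2.05e-05, and adjusted p = 0.162 with an estimated correlation). Of 22 members, VCAM1, TOX and the endocytic gene SNX9 (-1.40 ± 0.28) fell, the nuclear receptor gene NR4A3 rose (1.65 ± 0.34) and 18 did not pass (1 higher and 7 lower when adjusted over the list alone). MHC class II genes were lower (median -1.21, camera adjusted p = 3.43e-09, and adjusted p = 0.162 with an estimated correlation), with 4 of 11 members past the threshold and 7 when adjusted over the list alone. These were the invariant chain CD74 (-1.55 ± 0.30), HLA-DRA (-1.57 ± 0.35), HLA-DOA (-2.74 ± 0.56) and HLA-DRB1 (-1.21 ± 0.25), whose reads can be shared with near-identical copies. Cell cycle genes had a median of -1.55 (camera adjusted p = 1.75e-10, and adjusted p = 0.433 with an estimated correlation). Without effector library 4 this median was -0.675 and that of the exhaustion-associated genes -0.72, and without stem libraries 1 and 3, an alternative chosen after seeing the data, they were -0.875 and -0.68, and both lists still passed. AURKA and the replication licensing gene MCM5 (-2.27 ± 0.34) fell, 30 did not pass, and 5 were lower when adjusted over the list alone. DNA methylation machinery was lower (median -0.49, camera adjusted p = 0.000188, and adjusted p = 0.0794 with an estimated correlation). Of its 14 genes the demethylase gene TET1 (-1.74 ± 0.33) fell, and 5 were lower when adjusted over the list alone.

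The remaining function lists did not pass by camera in kidney. Inhibitory receptors had a median of -0.59 (camera adjusted p = 0.359), with CD200R1 lower, CEACAM1 higher (3.83 ± 0.73; reads can be shared with paralogs) and 4 higher and 2 lower when adjusted over the list alone. Costimulatory receptors and ligands had a median of 0.52 (0.404), with the activation receptor TNFRSF9, or 4-1BB, lower (-1.85 ± 0.28) and 3 higher and 2 lower when adjusted over the list alone. Chemokines and their receptors stood at 0.31 (0.266), with CCR7 alone past the threshold either way. Cytotoxic effector genes had a median of -0.59 (0.271), with 0 members past the threshold and 1 higher and 1 lower when adjusted over the list alone; NKG7, a cytotoxic granule gene, was at -1.45 ± 0.34 (adjusted p = 0.0609). Tissue residency genes were at 0.14 (0.47), glycolysis genes at 0.12 (0.55), oxidative phosphorylation genes at 0.02 (0.6) and heat shock genes at 0.41 (0.513), with 0 members past the threshold in any of the 4 lists, over all genes or adjusted over the list alone. Interferon-stimulated genes (0.18; 0.359), T-cell receptor signalling genes (0.10; 0.841) and apoptosis regulators (-0.28; 0.241) had 0 members past the threshold over all genes. Adjusted over the list alone, 1 interferon-stimulated gene was higher, 2 T-cell receptor signalling genes were higher and 2 lower, and 1 apoptosis regulator was lower.

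Of the markers of other cells, gamma-delta and MAIT cell markers were higher in kidney stem libraries as a list (median 2.44, camera adjusted p = 0.0071, and adjusted p = 0.498 with an estimated correlation). The median was 4.22 without effector library 4 and 1.605 without stem libraries 1 and 3. Over all genes 0 of 9 passed, and 3 were higher when adjusted over the list alone. SLC4A10, a bicarbonate transporter gene of MAIT cells, stood at 46.2 ± 83 CPM in stem and 0.115 ± 0.157 CPM in effector libraries (adjusted p = 0.113). Stem library 1 carried this mean: without it the other 3 stem libraries stood at 4.69 ± 3.04 CPM. NK-cell markers had a median of 0.87 (camera adjusted p = 0.0983), renal epithelial and clear cell carcinoma markers of 1.84 (0.334) and CD4 helper and regulatory T-cell markers of -0.85 (0.55). Myeloid markers (median 0.07, mean 0.04) and stromal and endothelial markers (median 0.68, mean 0.59) had a median above 0 and a camera direction below it, and neither passed (0.55 and 0.55). In these 5 lists 0 members passed over all genes, and adjusted over the list alone 1 CD4 helper and regulatory T-cell marker was higher and 1 lower. B-cell, epithelial, prostate epithelial and urothelial markers each had 1 gene tested, which did not pass over all genes, and erythrocyte markers had 0 genes tested. Adjusted over the list alone, the B-cell marker MS4A1 was higher and the urothelial marker TP63 lower. Kidney stem libraries 1 and 3 held more RNA of epithelial and renal genes than the other 2 stem libraries. The mean log2 CPM of the epithelial list was -0.57 and 1.60 in libraries 1 and 3 against -3.63 and -3.45 in libraries 2 and 4, and that of the renal list was 0.98 and 2.15 against -2.12 and -2.20. Libraries 1 and 3 also held less RNA of 2 genes of the sort. HAVCR2 had a log2 CPM of 1.645 and 0.794 in them against 4.878 and 4.994 in libraries 2 and 4. PDCD1 was at -0.086 and 0.529 against 2.825 and 2.832. Without libraries 1 and 3, an alternative chosen after seeing the data, 2 genes passed the threshold, 0 higher and 2 lower in stem. Each of the 108 genes called higher with all 8 libraries thus lost its call. Their median log2 fold change was 1.97, against 2.36 with all 8 libraries, on which they were chosen.

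The test was edgeR's quasi-likelihood F test on 8 libraries, and on simulated counts of 12579 genes it recovered 7.46%, 55.2% and 74.2% of genes changed 2-, 4- and 8-fold. The count of 191 moved by over 1.5 times when 1 library was left out: it was 51, 103, 48 and 359 without effector libraries 1, 2, 3 and 4, and 35, 94 and 55 without stem libraries 1, 2 and 3. IL7R lost its call without effector library 1 (edgeR adjusted p = 0.157) or 3 (0.126), or without stem library 1 (0.128), 2 (0.104), 3 (0.084) or 4 (0.0939), while VCAM1 passed in each of these fits. ATP1B1 rested in part on stem library 3, which held the most epithelial and renal RNA: without it the log2 fold change was 2.88 (adjusted p = 0.0564), and its call was also lost without effector library 1, 2 or 3 or stem library 1 (0.0641 to 0.123). LMNA and MPP7 lost their calls without effector library 1 (0.0576 each). Of the 10 largest decreases named above, VCAM1 and VANGL1 kept their calls throughout, and the other 8 lost them in 1 or more of these fits (0.0501 to 0.154). TCF7 lost its call without effector library 2 or 3 or stem library 1 or 2 (0.0535 to 0.075). Of the 18 called genes named through the lists alone, TOX, SORL1 and MCM5 kept their calls throughout, and the other 15 lost them in 1 or more fits (0.0501 to 0.155), the 4 MHC class II genes in 7 of 8.

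The second comparison set the 4 bladder stem libraries against the 2 bladder effector libraries. IL7R was again far higher in the stem libraries, at 1328 ± 336 CPM against 7.15 ± 0.967 CPM, a log2 fold change of 7.54 ± 0.43 (SE; edgeR adjusted p = 0.00249). CD226, a costimulatory receptor of T and NK cells (ENSG00000150637, chromosome 18, 69853274 to 69961773), was at 157 ± 55 CPM in stem (SD, n = 4) and 0.279 ± 0.00904 CPM in effector libraries (SD, n = 2; log2 fold change 9.12 ± 0.61, adjusted p = 0.00406). HAVCR2, a gene of the sort (ENSG00000135077, chromosome 5, 157085832 to 157109044), was at 77.8 ± 37 against 1385 ± 178 CPM and fell by 4.15 on the log2 scale (SE 0.43, and adjusted p = 0.0147). LAG3, an inhibitory receptor (ENSG00000089692, chromosome 12, 6772520 to 6778455), was at 159 ± 65.4 against 1172 ± 38.9 CPM, a log2 fold change of -2.88 ± 0.39 (adjusted p = 0.0321).

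Of 15688 genes tested, 111 passed the threshold, 57 higher and 54 lower in stem libraries, and 1753 had an unadjusted p below 0.05. The largest changes that follow were ranked among called genes with a mean log2 CPM of at least 2. Called genes below that level could change more, such as PTPRF at -9.34 ± 1.52 (edgeR adjusted p = 0.0477). The 10 largest increases included ENPP5 (9.85 ± 0.72), the corepressor TLE1 (8.76 ± 1.07), the Ras exchange factor RASGRF2 (8.61 ± 0.90), SSBP2 (8.27 ± 1.22), C10orf128 (8.21 ± 1.04), the chaperone clusterin, CLU (8.17 ± 1.18), and the oxidase subunit NCF4 (7.69 ± 1.25). The other 3 were CD226 and 2 genes with 3 or fewer counts in the effector libraries. The glycosyltransferase gene GALNT3 was 509-fold higher in stem libraries (95% counting interval 174 to 2470), and CHRM3-AS2, an antisense gene whose strand was not resolved, was 674-fold higher (231 to 3270). The 10 largest decreases so ranked were led by SEMA4A, a semaphorin (-5.33 ± 0.79), and UHRF1, which keeps DNA methylation through replication (-5.29 ± 0.81). HAVCR2, the microtubule regulator STMN1 (-3.41 ± 0.45), CD200R1 (-3.13 ± 0.36), the lysosome trafficking gene LYST (-3.10 ± 0.31), GGT1 (-2.94 ± 0.45; reads can be shared with paralogs), the antiviral gene OAS3 (-2.90 ± 0.45), LAG3 and SNAP47 (-2.86 ± 0.38) made up the rest. Groups did not overlap in 24.2% of the genes tested, where chance gives 13.3%, and in each of the 111 that passed.

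As a list the gate markers were lower in bladder stem libraries (median -0.83, camera adjusted p = 0.000563, and adjusted p = 0.159 with an estimated correlation). HAVCR2 fell, and 4 markers were lower when adjusted over the list alone. PDCD1 had a log2 fold change of -1.92 ± 0.65, CD8A of -0.90 ± 0.27, CD8B of -0.83 ± 0.28, CD28 of 0.71 ± 1.11 and CD3E of 0.05 ± 0.22, and none of the 5 passed over all genes. Stem-like and memory T-cell genes were higher (median 2.26, camera adjusted p = 8.18e-07, and adjusted p = 0.159 with an estimated correlation). IL7R, TCF7 (4.18 ± 0.66) and the chromatin organiser SATB1 (5.11 ± 0.50) rose, the costimulatory receptor CD27 fell (-2.74 ± 0.26), and 17 of 21 did not pass (9 higher and 2 lower when adjusted over the list alone). Exhaustion-associated genes were lower (median -1.45, camera adjusted p = 1.99e-06, and adjusted p = 0.0767 with an estimated correlation). TOX (-2.64 ± 0.37) and the T-box factor EOMES (-2.63 ± 0.25) fell and 20 did not pass, with 2 higher and 7 lower when adjusted over the list alone. VCAM1 was at 34.7 ± 23.9 against 1635 ± 78.6 CPM and missed the threshold (adjusted p = 0.0829). Cytokine receptors were higher (median 0.92, camera adjusted p = 8.33e-06, and adjusted p = 0.0883 with an estimated correlation). IL7R, IL18R1 (7.33 ± 1.15) and TGFBR3 (4.11 ± 0.62) rose and 18 did not pass, with 7 higher when adjusted over the list alone.

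Cell cycle genes had the lowest median of all function lists in bladder, -4.34 (camera adjusted p = 7.5e-24, and adjusted p = 0.0767 with an estimated correlation). STMN1 and MCM5 (-2.12 ± 0.31) fell, 30 of 32 did not pass, and 16 were lower when adjusted over the list alone. The mean log2 CPM of the list was 0.79 ± 0.81 in stem (SD, n = 4) and 5.82 ± 0.35 in effector libraries (n = 2). Interferon-stimulated genes were lower (median -1.52, camera adjusted p = 4.62e-14, and adjusted p = 0.0768 with an estimated correlation). The antiviral genes OAS1 (-2.85 ± 0.38), OAS3, MX1 (-2.54 ± 0.41) and IFI6 (-2.47 ± 0.40) fell and 22 did not pass, with 8 lower when adjusted over the list alone. MHC class II genes were lower (median -2.43, camera adjusted p = 1.08e-12, and adjusted p = 0.0959 with an estimated correlation), with CD74 (-2.61 ± 0.32) past the threshold, 10 that did not pass and 7 lower when adjusted over the list alone. Glycolysis genes were lower (median -0.64, camera adjusted p = 0.00175, and adjusted p = 0.159 with an estimated correlation). Pyruvate kinase, PKM (-1.88 ± 0.26), fell and 16 did not pass, with 1 higher and 6 lower when adjusted over the list alone. DNA methylation machinery was lower (median -0.72, camera adjusted p = 0.000498, and adjusted p = 0.159 with an estimated correlation), with UHRF1 past the threshold among 14 genes, over all genes and adjusted over the list alone. Without stem library 4 this median was -1.246.

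Immediate early genes were higher in bladder stem libraries (median 1.45, camera adjusted p = 5.24e-21, and adjusted p = 0.0959 with an estimated correlation). The early growth response factor EGR1 (4.10 ± 0.68), the activation marker CD69 (2.16 ± 0.33) and the stress phosphatase subunit PPP1R15A (1.73 ± 0.24) rose and 17 did not pass, with 19 of 20 higher when adjusted over the list alone. Heat shock genes had a median of 1.78 (camera adjusted p = 1.6e-10, and adjusted p = 0.159 with an estimated correlation), 0 of 13 past the threshold over all genes and 12 higher when adjusted over the list alone. Ribosomal protein genes had a median of 0.88 (camera adjusted p = 8.77e-13, and adjusted p = 0.199 with an estimated correlation), with 0 past the threshold and 8 higher when adjusted over the list alone. Tissue residency genes were higher (median 0.56, camera adjusted p = 0.000165, and adjusted p = 0.0959 with an estimated correlation). CD69 and ITGAE, the CD103 integrin that binds E-cadherin (3.55 ± 0.58), rose and 10 did not pass, with 5 higher when adjusted over the list alone. Tissue egress genes were higher as a list too (median 2.85, camera adjusted p = 4.77e-05, and adjusted p = 0.212 with an estimated correlation). Of its 9 genes 0 passed over all genes and 5 were higher when adjusted over the list alone. Chemokines and their receptors were higher (median 0.70, camera adjusted p = 0.00534, and adjusted p = 0.17 with an estimated correlation). XCL2 rose (3.72 ± 0.46; reads can be shared with XCL1) and 16 did not pass, with 5 higher and 2 lower when adjusted over the list alone. This call was lost without effector library 1 (0.0519) or 2 (0.14).

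Of 29 lists tested in bladder, 17 passed by camera, 0 with an estimated correlation and 13 by fry. The other function lists did not pass by camera in bladder. Inhibitory receptors had a median of -0.28 (camera adjusted p = 0.052), with HAVCR2, CD200R1 and LAG3 lower, LAIR1 higher (3.39 ± 0.55) and 3 higher and 5 lower when adjusted over the list alone. Cytotoxic effector genes stood at 0.07 (0.8), with granzyme K, GZMK, lower (-2.34 ± 0.35), the NK receptor subunit KLRD1 higher (4.18 ± 0.63) and 5 higher and 5 lower when adjusted over the list alone. Costimulatory receptors and ligands had a median of -0.10, a mean of 0.61 and a camera direction below 0 (0.769), with CD226 higher, CD27 lower and 3 higher and 4 lower when adjusted over the list alone. Oxidative phosphorylation genes were at -0.06 (0.682), T-cell receptor signalling genes at -0.25 (0.0535) and apoptosis regulators at -0.21 (0.0811), with 0 members past the threshold over all genes. Adjusted over the list alone, 1 T-cell receptor signalling gene and 1 apoptosis regulator were lower.

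**Figure D2:**
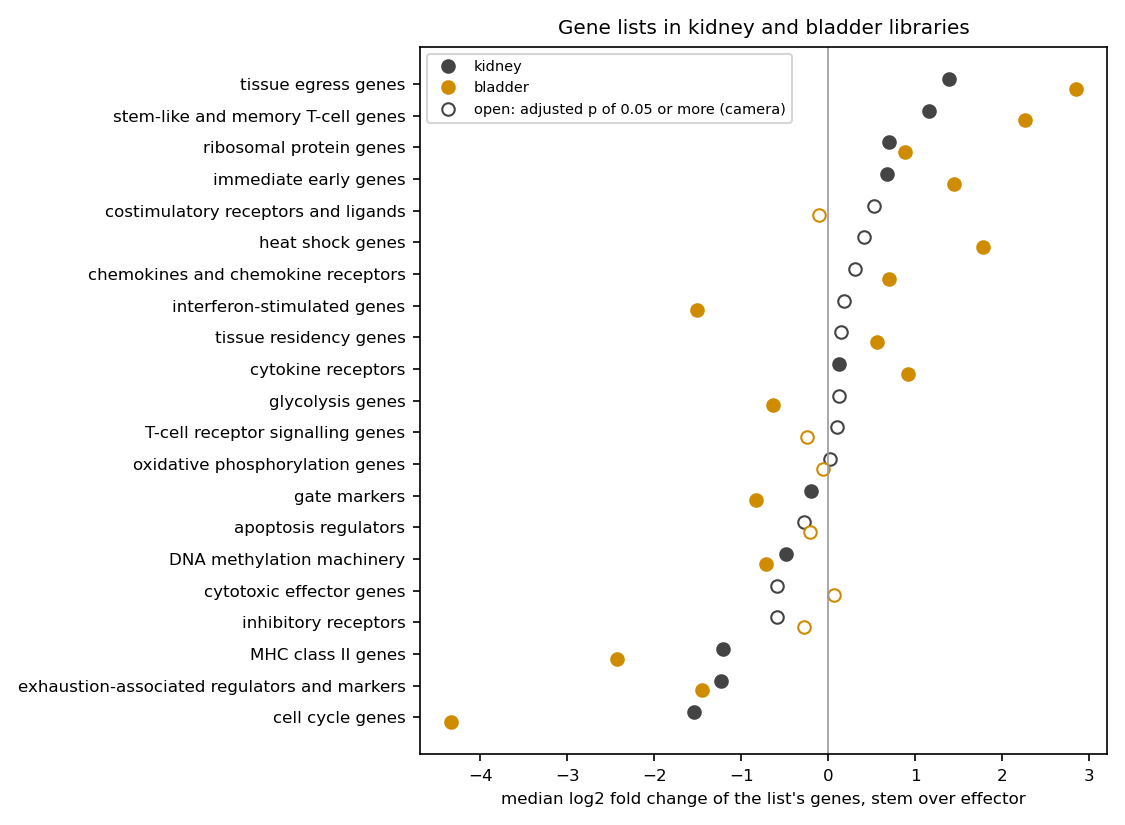
Median log2 fold change of stem over effector libraries for the 20 function lists and the gate markers, in kidney (black) and bladder (orange), filled where the camera adjusted p was below 0.05 and open where it was not. Cell cycle genes had the lowest median in both tumours, -1.55 in kidney and -4.34 in bladder, and tissue egress genes the highest, 1.38 and 2.85.

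Among markers of other cells, NK-cell markers were higher in bladder stem libraries (median 3.21, camera adjusted p = 0.000591, and adjusted p = 0.228 with an estimated correlation). The secreted protein gene SPON2 rose (4.43 ± 0.73) and 9 did not pass, with 3 higher when adjusted over the list alone. Gamma-delta and MAIT cell markers were higher (median 2.99, camera adjusted p = 0.000274, and adjusted p = 0.199 with an estimated correlation). Without effector library 1 this median was 4.86. The NK and MAIT receptor KLRB1, or CD161 (5.37 ± 0.79), rose and 9 did not pass, with 2 higher when adjusted over the list alone. Epithelial markers had a median of 2.95 (0.554) and B-cell markers of 0.07 (0.769), with 0 members past the threshold. Renal markers (median 2.18), CD4 helper and regulatory markers (1.11) and myeloid markers (0.64) had a median above 0 and a camera direction below it, and stromal markers a median of -0.20 and a mean of 1.79. None of these 4 lists passed (0.688, 0.8, 0.109 and 0.561), and GGT1 was their only member past the threshold. Genes with 3 or fewer counts in 1 group, set at their bound, left these medians as they were. Urothelial and prostate epithelial markers had 1 gene tested and erythrocyte markers 2, and 0 of them passed over all genes. The urothelial gene, S100P, had 0 counts in the effector libraries and was at least 49.6-fold higher in stem, and it passed when adjusted over the list alone. Bladder stem library 3 had a mean log2 CPM of 4.45 over the epithelial list, against -3.08 to -2.01 in the other 3 stem libraries, and held 396.2 CPM of the claudin gene CLDN4, where the other 3 held at most 0.71.

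The median log2 fold change over all bladder genes was 0.094, and -0.236 with limma-voom. On simulated counts of 14213 genes the test recovered 0%, 3.03% and 45.5% of genes changed 2-, 4- and 8-fold. The count of 111 was 15 and 16 without effector libraries 1 and 2, and 6, 53, 71 and 22 without stem libraries 1 to 4. HAVCR2 lost its call without stem library 1 (edgeR adjusted p = 0.06), and LAG3 without effector library 1 (0.085) or 2 (0.0748) or stem library 1 (0.06), 2 (0.0709) or 4 (0.0866). Of the 10 largest increases named above, only ENPP5 and CD226 kept their calls throughout. The other 8 lost them in 1 or more fits (0.0567 to 0.24), CLU and NCF4 in all 6. Each of the 10 largest decreases named above lost its call in 1 or more fits (0.0502 to 0.565), UHRF1 and GGT1 in all 6. So did each of the called genes named through the lists alone (0.0502 to 0.604), among them TCF7 (0.06 to 0.238) and TOX (0.058 to 0.143), which passed in none of the 6 fits.

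The kidney result was then carried to the bladder libraries, with no library in common. Of the 104 genes higher in kidney stem that were tested in both tumours, 98 had a fold change above 0 in bladder, with a median of 1.76. Of the 81 lower in kidney stem, 75 were below 0, with a median of -1.83. These shares, 94.2% and 92.6%, compare with 62.5% of the same sign over all 12070 shared genes. By camera the kidney-higher genes were higher in bladder (p = 9.3e-34; p = 0.00248 with an estimated correlation; fry p = 0.00126) and the kidney-lower genes lower (p = 4.83e-29; p = 0.000293 with an estimated correlation; fry p = 3.41e-05). In both tumours 17 genes passed the threshold, all in the same direction: 8 higher, where independent lists would share 0.483, and 9 lower, where they would share 0.349. Genes of this overlap were named after their values were seen. The higher genes were ENPP5, GALNT3, MPP7, IL7R, TCF7, DPP4, STAT4 and MYBL1. DPP4, a dipeptidyl peptidase gene, stood at 3.21 ± 0.62 in kidney and 3.66 ± 0.51 in bladder. STAT4 of interleukin-12 signalling stood at 2.70 ± 0.45 and 2.36 ± 0.30. The lower genes were CD74, TOX, CD200R1, LYST, MCM5, PTPRF, HIVEP1, GFOD1 and the cell cycle kinase CDK6 (-1.81 ± 0.28 and -2.59 ± 0.42). Gamma-delta and MAIT cell markers were higher in stem libraries of both tumours as well, with list medians of 2.44 and 2.99, and these libraries do not show which cells carried the 17 genes. Of the 20 genes ranked by their change in kidney, with a mean log2 CPM of at least 2 there, MPP7, IL7R, CD200R1 and PTPRF passed in bladder. TANC2 and NHSL2 had 0 counts in the bladder effector libraries and were at least 174-fold and 197-fold higher in stem (3 counts over the group as the floor), and did not pass. Across the shared genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.452 and a Spearman correlation of 0.381. In fits chosen after the data were seen, the kidney-higher median in bladder rose to 2.897, 2.748 and 2.897 when the genes were chosen without kidney effector library 1, effector library 3 or stem library 3.

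**Figure D3:**
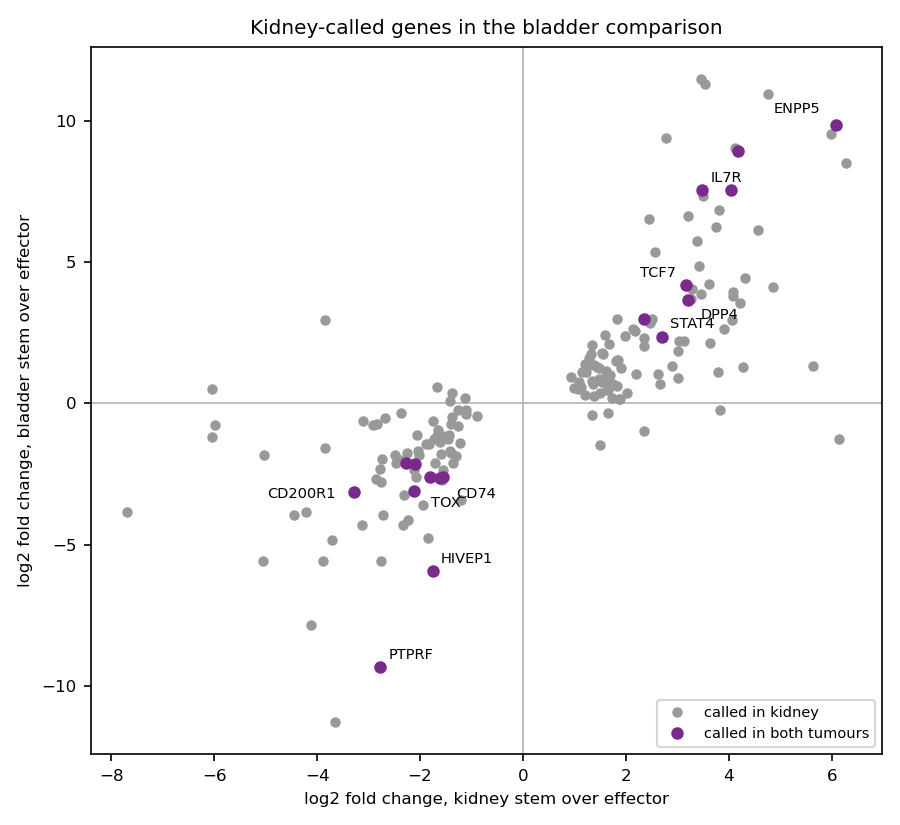
Log2 fold change of stem over effector libraries in kidney (horizontal) and bladder (vertical) for the genes past the threshold in kidney, with those past it in both tumours in purple; genes with few bladder effector counts are drawn at their fitted value. Of the 104 kidney-higher genes 98 lie above 0 in bladder, and of the 81 kidney-lower genes 75 lie below 0.

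Whether the difference between subsets itself differed between tumours was tested in 1 fit of all 14 kidney and bladder libraries. Of 20611 genes, 3 passed by edgeR, all with a lower stem to effector ratio in bladder, and they were named after their values were seen. They are cell division genes: KIF23, a kinesin of cytokinesis (ENSG00000137807, chromosome 15, 69414349 to 69448427, and adjusted p = 0.014), NEK2, a centrosomal kinase (ENSG00000117650, chromosome 1, 211658256 to 211675621, and adjusted p = 0.0453), and SHCBP1 (ENSG00000171241, chromosome 16, 46578591 to 46621379, and adjusted p = 0.0453). In bladder stem libraries they had 2, 2 and 1 counts in all, and the bladder effector to stem ratios were 2480 (95% counting interval 687 to 20500), 1020 (282 to 8440) and 2770 (496 to 109000). In kidney KIF23 was at 20.2 ± 17.9 CPM in stem and 44.3 ± 47.1 in effector libraries (SD, n = 4 each), NEK2 at 5.96 ± 1.92 and 7.41 ± 7.08, and SHCBP1 at 3.64 ± 2.05 and 10.95 ± 8.98. Of the genes named above, SEMA4A had a difference of -3.79 ± 0.75 (adjusted p = 0.0778), PTPRF of -6.42 ± 1.31 (0.0907) and IL7R of 4.22 ± 0.95 (0.175), and none passed.

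By camera 11 of 31 lists differed between the tumours, and the call of none held with an estimated correlation or by fry. Cell cycle genes had a lower stem to effector ratio in bladder than in kidney (median difference -2.17, camera adjusted p = 3.42e-15, and adjusted p = 0.212 with an estimated correlation). It was also lower for interferon-stimulated genes (-1.63, 3.42e-15, and adjusted p = 0.212 with an estimated correlation), MHC class II genes (-0.87, 0.00109, and adjusted p = 0.355 with an estimated correlation) and glycolysis genes (-0.32, 0.0236, and adjusted p = 0.629 with an estimated correlation). The ratio was higher in bladder for heat shock genes (1.63, 3.78e-07, and adjusted p = 0.355 with an estimated correlation), immediate early genes (1.12, 3.78e-07, and adjusted p = 0.212 with an estimated correlation), stem-like genes (1.27, 0.00207, and adjusted p = 0.226 with an estimated correlation) and cytokine receptors (0.52, 0.00426, and adjusted p = 0.264 with an estimated correlation). It was also higher for NK-cell markers (2.64, or 2.38 with genes near 0 counts at their bound; 0.0393, and adjusted p = 0.49 with an estimated correlation), tissue residency genes (1.20, 0.0393, and adjusted p = 0.402 with an estimated correlation) and ribosomal protein genes (0.22, 0.0472, and adjusted p = 0.82 with an estimated correlation). In each of these 11 lists 0 members passed over all genes. Adjusted over the list alone, 3 cell cycle genes were lower, among them AURKB (-7.62 ± 1.94), 1 MHC class II gene and 1 stem-like gene were lower. By the same count 5 immediate early genes, 3 stem-like genes, 3 cytokine receptors, 2 NK-cell markers and 1 heat shock gene were higher. The other 20 lists tested had camera adjusted p from 0.0649, for urothelial markers, to 0.93. Adjusted over the list alone, 1 inhibitory receptor, 1 costimulatory gene and 1 urothelial marker were higher in these lists, and 1 costimulatory gene, 1 gene of DNA methylation, 1 of T-cell receptor signalling and 2 renal markers were lower. With genes near 0 counts at their bound the median of the urothelial markers went from 7.29 to 4.41, of the renal markers from 0.09 to -1.49, of the prostate epithelial markers from 0.30 to -0.49 and of the B-cell markers from -0.20 to -0.80. Median, mean and test differed in sign for inhibitory receptors, costimulatory genes, apoptosis regulators, B-cell, myeloid and renal markers.

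Tumour, count table and library kit cannot be told apart in this contrast, and the median difference over all genes was 0.197. This median was -0.226 with a block on replicate number, -0.172 with no low-count filter, -0.128 without bladder stem library 3 and -0.086 with limma-voom. In the other settings it stayed above 0. The count of 3 was 0 without kidney effector library 1 or 2, 1 without kidney effector library 3, kidney stem library 1, 2 or 4, bladder effector library 1 or bladder stem library 4. It was 7, 5, 14 and 66 without kidney stem library 3 and bladder stem libraries 1, 2 and 3, and DESeq2 called 476. KIF23 lost its call without kidney effector library 1 (0.0513) or 2 (0.0683) or bladder stem library 4 (0.0548). NEK2 (0.0548 to 0.176) and SHCBP1 (0.0508 to 0.176) each lost theirs in 10 of the 14 fits without 1 library. On simulated counts of 19513 genes this test recovered 0%, 2.99% and 21.2% of genes changed 2-, 4- and 8-fold, with 11.1% false calls, so few calls say little about how alike the tumours are.

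The prostate stem libraries were set against the kidney stem libraries, 2 against 4, in 1 fit with the kidney effector libraries. By edgeR 0 of 18703 genes passed (smallest adjusted p 0.119), 1671 had an unadjusted p below 0.05, limma-voom called 0 and DESeq2 194. The smallest p-values among higher genes belonged to WDR61, a transcription elongation factor subunit (2.47 ± 0.40, and adjusted p = 0.119), TET1 (2.20 ± 0.38; 0.122), the histone gene HIST1H2BD (2.47 ± 0.45; reads can be shared with its copies), DCLRE1B (2.43 ± 0.49) and MSANTD4 (1.93 ± 0.42). Among lower genes they belonged to HLA-DRB1 (-2.22 ± 0.35; 0.119), CYSTM1 (-4.02 ± 0.77), SNHG3 (-1.95 ± 0.45), the respiratory chain gene UQCRFS1 (-2.46 ± 0.57) and DTL (-2.86 ± 0.67), none of which passed. Genes of the sort did not pass either: HAVCR2 was at 7.22 ± 2.31 CPM in prostate and 16.4 ± 16.3 CPM in kidney stem libraries, and PDCD1 at 2.29 ± 0.941 and 4.06 ± 3.42.

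By camera 7 of 30 lists differed, and no call held with an estimated correlation or by fry. MHC class II genes were lower in prostate stem libraries (median -1.31, camera adjusted p = 5.42e-07, and adjusted p = 0.712 with an estimated correlation). So were cell cycle genes (-1.35, 3.68e-06, and adjusted p = 0.712 with an estimated correlation), oxidative phosphorylation genes (-0.49, 0.00289, and adjusted p = 0.712 with an estimated correlation), ribosomal protein genes (-0.32, 0.00161, and adjusted p = 0.712 with an estimated correlation) and glycolysis genes (-0.52, 0.00673, and adjusted p = 0.712 with an estimated correlation). Heat shock genes were higher (1.22, 5.42e-07, and adjusted p = 0.712 with an estimated correlation), and so were gamma-delta and MAIT cell markers (1.06, 0.018, and adjusted p = 0.712 with an estimated correlation). Over all genes 0 members of any list passed, and adjusted over the list alone 5 MHC class II genes and 1 gene each of the oxidative phosphorylation, exhaustion, costimulatory and renal lists were lower and TET1 was higher. The lists that did not pass lay between a camera adjusted p of 0.0792 and 0.94, with stem-like genes at a median of -0.27 (0.726) and exhaustion-associated genes at 0.04 (0.471). For exhaustion-associated genes, B-cell, myeloid and NK-cell markers, median, mean and test differed in sign. Epithelial markers had a median of -5.19, or -5.24 with genes at 0 counts at their bound (0.0792), beside the higher epithelial levels of kidney stem libraries 1 and 3. Leaving out those 2 libraries, chosen after seeing the data, gave 8 genes, leaving out kidney stem library 1 alone gave 1. On simulated counts of 17231 genes the test recovered 4.48%, 31.3% and 75.8% of genes changed 2-, 4- and 8-fold.

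The prostate libraries were last placed on the axis between the kidney subsets, as the mean log2 CPM of genes higher in kidney stem minus that of genes higher in kidney effector. With the 191 genes above, the score was 1.91 ± 0.24 in prostate stem (SD, n = 2), 2.15 ± 0.44 in kidney stem and -2.82 ± 0.50 in kidney effector libraries (n = 4 each). The kidney values are circular because the genes were chosen on them. With the 100 genes of smallest p in each direction, and each kidney library scored by genes chosen without it, the scores were 1.96 ± 0.28, 1.74 ± 1.17 and -2.01 ± 1.46. Prostate stem libraries differed from kidney stem by 0.22 (exact two-sided permutation p = 0.933) and from kidney effector by 3.97 (exact p = 0.0667, the smallest that 2 against 4 libraries can give, so this test cannot reach 0.05).

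**Figure D4:**
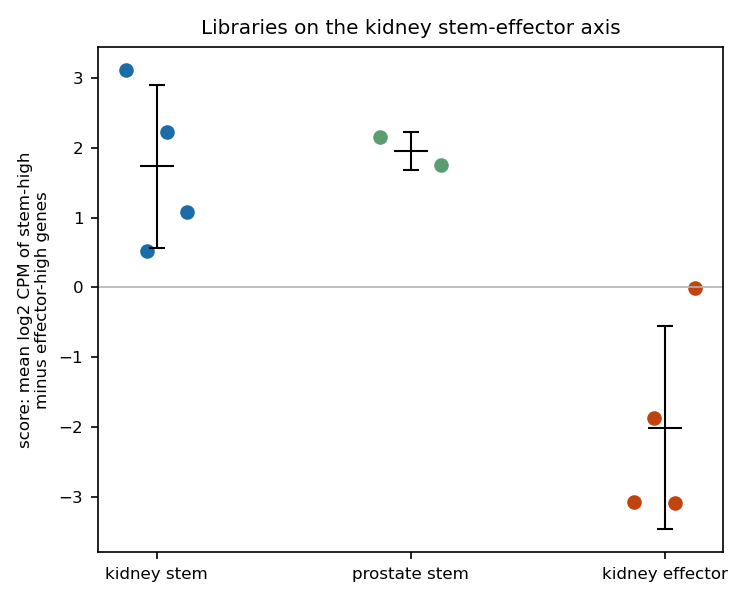
Score of each library on the kidney axis (points), the mean log2 CPM of the 100 genes of smallest p among those higher in kidney stem minus that of the 100 among those higher in kidney effector, with kidney libraries scored by genes chosen without them and the group mean and SD in black. Both prostate stem libraries lie within the range of the kidney stem libraries and above every kidney effector library.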

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

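The ratio of mitochondrial ribosomal RNA to other mitochondrial RNA, the surrogate variable the fits without kidney stem libraries 1 and 3, and the genes chosen on part of the kidney libraries were tests chosen only after the data were seen. A library was singled out where it lay far from the other 3 of its group, which chance gives in about 1 in 20 groups: of 213 groups of values tested, 17 had such a library, where chance gives 10.7. Genes were singled out where the subset difference differed between kidney and bladder.

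Among kidney libraries, effector library 2 had 69.3 M counts, where the other 3 effector libraries had 15.3 to 18.8 M (M, mega-counts). Effector library 1 had 64.86% of its counts in its top 50 genes, where the others had 59.88% to 60.06%. The mean log2 CPM of stem-like genes was 4.018 in effector library 1 against 3.514 to 3.594, that of tissue egress genes 1.64 in effector library 2 against 2.557 to 2.715, and that of gamma-delta and MAIT cell markers 1.541 in effector library 4 against -0.464 to -0.131. Effector library 3 had a log2 CPM of -0.073 for LMNA against 2.195 to 2.625. Effector library 4 had 4.785 for GPR183 against 2.942 to 3.151 and 4.801 for CD200R1 against 7.295 to 7.803. Stem library 1 had a mean log2 CPM of -2.793 over erythrocyte markers, where the other 3 stem libraries stood at -3.795. That value is the floor of 0 counts, so any reads of these markers in 1 library alone would have singled it out.

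Among bladder stem libraries, library 1 had a mean log2 CPM of 3.397 over stem-like genes, against 4.852 to 5.141 in the others, and library 2 had 4.208 over costimulatory genes, against 5.198 to 5.254. Library 3 had 4.999 over exhaustion-associated genes against 4.188 to 4.259, 4.452 over epithelial markers against -3.081 to -2.011, and -1.015 over renal markers against -2.727 to -2.437. Library 4 had a log2 CPM of 0.164 for VCAM1 against 5.328 to 5.846, -2.859 for SNX18 against 2.672 to 3.346, and 0.074 for AMER1 against -3.836 in each of the others. For AMER1 the others stood at the floor of 0 counts, so any reads in 1 library alone would have singled it out.

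The stem to effector difference was lower in bladder than in kidney for NEK2 (-9.2403), KIF23 (-9.7556) and SHCBP1 (-8.9424), as fitted log2 values that depend on the prior count because bladder stem libraries had 1 or 2 counts of each gene. Tumour, table and library kit cannot be told apart for these 3 genes.

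The first pattern weighed is the number of genes that differed between kidney stem and effector libraries. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, called as many as 191 genes, and the highest other called 8. This share is under 0.05 and is the smallest that 35 splits can give. It argues against chance only if the 8 libraries are independent, which the labels used here do not state. With a surrogate variable as covariate, 190 of the 191 genes stayed past the threshold. But this covariate was balanced over the groups (means -0.024 in stem and 0.024 in effector libraries), so it could not take away a group effect. A hidden structure that follows the groups cannot be told apart from the subsets. The covariate set libraries 1 and 3 of both subsets (-0.5566 to -0.2368) apart from libraries 2 and 4 of both (0.1904 to 0.4147). The split that called 8 genes followed the same division. Libraries of 1 subset were thus not alike replicates, and the cause of this division was not tested. Without stem libraries 1 and 3, which held more epithelial and renal RNA, the 108 higher genes had a median log2 fold change of 1.969 (quartiles 1.348 to 3.34, median SE 0.454). With all libraries it was 2.355 (1.597 to 3.514, SE 0.39). This argues neither way, as these genes were chosen on all 8 libraries and had groups that did not overlap. Without libraries 1 and 3, 2 genes passed, 0 higher and 2 lower in stem, so each of the 108 lost its call. Without 4 other pairs of stem libraries 0, 0, 2 and 7 genes passed, but 342 did without libraries 2 and 4. For 100 genes chosen on stem libraries 1 and 3 and 2 effector libraries, the median in the other 4 libraries was 0.718 to 1.514 over the 6 choices. The rule set for this test took under 0.5 in each as RNA of other cells being the whole cause, and 1 or more in each as against it. Neither was met. A low median could not have singled out that RNA, since libraries 1 and 3 also differed in HAVCR2 and PDCD1. No median was under 0.5, and 66 to 94 of the 100 genes were above 0. The lowest lower quartile was -0.477. Most of these genes were thus higher in stem libraries 2 and 4 as well. By the rule set, this does not decide whether that RNA in libraries 1 and 3 was the whole cause. A part played by that RNA cannot be told apart from a biological difference between the subsets here.

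The second pattern is the share of mitochondrial ribosomal RNA, near 50% of kidney and prostate counts and near 1% of bladder counts. More mitochondrial RNA per cell would raise the other mitochondrial RNA alike, but in a prediction written after the ratios were seen, the ratio of ribosomal to other mitochondrial RNA was 26.1 times as high in the lowest kidney or prostate library as in the highest bladder library. A kit that also copies RNA without a poly(A) tail would raise replication-dependent histone RNA, and the lowest kidney effector library held 0.663 of the share in the highest bladder effector library (means 0.0323% ± 0.0149, n = 4, and 0.0309% ± 0.00609, n = 2, of counts outside mitochondrial ribosomal RNA). A test on 5 nuclear RNAs without a poly(A) tail gave 0.12, but this and the histone test, which both met the condition written beforehand against such a kit, were set to undecided after the results were seen: RN7SL2 and RMRP had 0 counts over all 16 libraries, and RN7SK, counted in all 16, took 0.00313% to 0.0188% of these counts in kidney effector against 0.000423% to 0.000469% in bladder effector libraries, as such a kit would give, though stem libraries overlapped (0.00024% to 0.0032% and 0.000931% to 0.00196%). Such a kit, a difference in another step, between tumours or in the authors' counting may be the source, and these cannot be told apart here.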

How the results depend on the processing

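The surrogate variable, the fits without kidney stem libraries 1 and 3 or bladder stem library 3 together, and the scores by genes chosen without the library scored were tests chosen only after the data were seen. So were the fits without 1 library of the kidney effect in bladder, and the list tests with other size factors. Where no cause is named below, the cause was not tested. The genes higher and lower in kidney kept their direction in bladder in all 15 alternatives that could move it, 14 without 1 library and 1 with a kidney threshold of 0.1 (1.272 and -1.469), with medians of 1.434 to 2.897 and -2.737 to -1.666 over fits without 1 library.

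The number of genes past the threshold moved by over 1.5 times under several settings. In kidney it was 922 with no low-count filter, 800 with DESeq2, 543 with limma-voom, 62 for a change beyond 1.5-fold, 490 with a surrogate variable, 2 without stem libraries 1 and 3, and 35 to 359 when 1 library was left out. In bladder it was 328 with no filter, 1006 with DESeq2, 629 with limma-voom, 47 beyond 1.5-fold, and 6 to 71 when 1 library was left out. The share of higher genes in bladder was 51.4%, and 65% with DESeq2, 37.7% with limma-voom and 66.7% with the block on replicate number. For the difference between tumours it was 197 with no filter, 1 with a filter at 1 CPM, 476 with DESeq2, 11 with limma-voom, 8 without abundant gene classes, 55 without kidney stem libraries 1 and 3 and bladder stem library 3, and 0 to 66 when 1 library was left out. For prostate it was 181 with no filter, 194 with DESeq2, 8 without kidney stem libraries 1 and 3, and 0 to 1 when 1 library was left out. Fits without a library hold fewer samples, and a test beyond 1.5-fold asks for more than a change.

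A block on replicate number called 338 genes in kidney, 1332 in kidney with limma-voom, 45 in bladder and 142 for the difference between tumours. The check did not show that the numbers pair the samples: the deviations of same-numbered kidney libraries correlated at 0.083 to 0.266, 3 of 4 pairs over 0.1, against up to 0.252 between other numbers, and 5 of 8 libraries correlated best with their own number. Between subsets, kidney libraries numbered 1 or 3 correlated with each other at 0.135 to 0.252, and those numbered 2 or 4 at 0.002 to 0.266. Kidney libraries numbered 1 or 3 correlated with those numbered 2 or 4 at -0.248 to -0.013. In bladder the 2 pairs correlated at -0.011 and 0.015.

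The prostate score less that of kidney stem was -0.239, and 0.223 with kidney libraries scored by genes chosen without them; less that of kidney effector it was 4.724 and 3.971. Heat shock genes in kidney, which did not pass, went to a median of -0.534 (adjusted p = 0.00575) without stem libraries 1 and 3. The call of the interaction lists was lost for tissue residency with other size factors (0.0537 and 0.0533), for ribosomal protein genes (0.0848 and 0.0546), and without the 3 libraries named above for stem-like genes (0.0914), tissue residency (0.164), ribosomal protein genes (0.459) and NK-cell markers (0.182). Without those 3 libraries the interaction medians were 0.823 for cytokine receptors, 0.783 for tissue residency, -3.264 for cell cycle, -0.62 for glycolysis, 0.074 for ribosomal protein genes and 1.546 for NK-cell markers. Without kidney stem libraries 1 and 3 the prostate medians were -0.806 for MHC class II genes, 2.434 for heat shock genes and 2.76 for gamma-delta and MAIT cell markers, and in kidney the median of the gate markers was 0.143 (adjusted p = 0.275) and of the cytokine receptors 0.449.

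Over fits without 1 library, calls of named genes were kept in 105 and lost in 55 cases in kidney, kept in 49 and lost in 89 in bladder, and kept in 19 and lost in 23 for the difference between tumours, with no change of direction. Depth limits genes near 0 counts, whose ratios rest on 1 to 3 counts.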

Other observations

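The tests of the list without TRAV1-2 and of the share without each library were chosen only after the result was seen. The share of T-cell receptor alpha counts in a variable segment is a measure that the marker lists do not give, though TRAV1-2 itself belongs to the gamma-delta and MAIT list. TRAV1-2, the variable segment used by the invariant receptor of MAIT cells, took 8.56% ± 13.5 of TRAV counts in kidney stem libraries (SD, n = 4) and 0.355% ± 0.295 in kidney effector libraries (n = 4), with every stem library above every effector library (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give). In bladder it took 7.42% ± 6.35 of stem (n = 4) and 0.626% ± 0.181 of effector TRAV counts (n = 2), again without overlap (exact p = 0.133, where the smallest possible is 0.0667). Without stem library 1 the stem share was 1.8% ± 0.851 in kidney and 4.55% ± 3.33 in bladder. In prostate stem libraries it took 14.4% ± 13.6 (n = 2).

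The third pattern weighed is the higher level of gamma-delta and MAIT cell markers in stem libraries of both tumours. MAIT cells inside the stem gate may be the source, as a hypothesis: the share of TRAV counts in TRAV1-2 was 8.21 percentage points higher in kidney stem than effector libraries (SE 6.77) and 6.79 points higher in bladder (SE 3.18), in a test that could have come out the other way. Stem library 1 carried most of this in kidney and part of it in bladder: without it the difference was 1.45 points in kidney (SE 0.513) and 3.92 in bladder (SE 1.93), and stem and effector libraries still did not overlap. TRAV1-2 belongs to the list, and without it 7 of 8 markers in kidney and 9 of 9 in bladder were higher in stem libraries, with medians of 1.92 and 3.06 (camera p = 0.00818 and 0.000407; p = 0.211 and 0.137 with an estimated correlation). The SD over stem libraries was above the mean in kidney and near it in bladder, and the sort did not name a marker that would remove these cells.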
